A study of Rattus norvegicus with 20 samples.

How the data were processed

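RNA from the fat layer of rat milk was sequenced as 20 libraries: 5 from saline and 5 from LPS dams on postnatal day 10, 2 h after the injection, and 5 and 5 on postnatal day 11, 24 h after it. Per the labels, milk was let down with 0.2 mL of oxytocin (20 USP units per mL), and stranded mRNA libraries made from at least 190 ng of RNA were read as 100 bp single ends on 2 lanes; the labels give a target depth, not the depth reached. The labels describe 5 biological replicates per group, from 7 saline and 7 LPS dams, of which 3 and 3 were milked at both times. The libraries of the 2 days are therefore not fully independent, and the columns name no dam, so that a dam could not be entered in a model. Per the submitters' processing notes, the authors used DESeq2 and the rat assembly rn6, both without a version; the aligner, the counting tool and the annotation are not given in the sources used here.

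The authors deposited a table of log2-scale expression values for 16748 genes in 20 columns, all of which could be assigned to a group. Its name calls the values rlog. The values themselves have a single lowest value of 5.46 shared by all columns, holding 30.4% of all entries, and a highest of 24.6, which is the form of a variance-stabilizing transformation. They were used as deposited log2-scale values in the tests, and the transformation was inverted to give normalised counts per library. These normalised counts were not turned back into whole reads. Each library was divided by its smallest positive value. After that, between 0.28% and 8.00% of low values fell within 0.02 of a whole number, where 4% would by chance. No other scaling was tried. Depth per library and counting error are therefore unknown, and the precision given is the spread between libraries. The authors also deposited a table for each day with the genes of their LPS comparison whose unadjusted p was under 0.05. In it, per the file headers, the base mean is in another unit (the mean of the authors' normalised counts), the fold change and its standard error are log2 values, the Wald statistic is a score, and the p-value is given raw and adjusted. These tables were read for the genes they list and were not used in any test here. Gene names are the deposited symbols. A reference table of gene names, which held 16619 of the deposited IDs, served to match list members by synonym. It also served to restore, by ID, 25 symbols that a spreadsheet had turned into dates. There was 1 symbol shared by 2 IDs.

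The groups, comparisons, tests, gene lists, naming rule and most alternative settings were fixed before the data were examined. A single model with 4 groups was fitted to each gene with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation along a mean-variance trend. The comparisons were LPS against saline at P10 and at P11, the difference of these effects, and P11 against P10 in saline and in LPS dams. P-values are two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The planned filter, a mean value of at least 3, removes no gene on this scale, since the lowest value is above it. A total of 2726 genes at the lowest value in every library were left out, a choice made after seeing that including them disturbed the trend, and 14022 were tested. Errors of log2 differences are the model's SE, and errors of normalised counts and library measures are SD between libraries.

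The 30 gene lists were written from general knowledge of lactation, inflammation, stress and cell types. They cover milk proteins and globule membrane, lactose synthesis and sugar transport, fatty acid and triglyceride synthesis, cholesterol synthesis, prolactin and STAT5 signalling, ion and micronutrient transport, tight junctions, acute phase and antimicrobial genes, NF-kB and Toll-like receptor signalling, cytokines and chemokines, interferon response, STAT3 signalling and involution, glucocorticoid response, immediate early genes, unfolded protein response, oxidative stress response, heat shock response, circadian clock, cytosolic ribosomal proteins, nuclear oxidative phosphorylation, mitochondrially encoded genes, and markers of neutrophils, macrophages and monocytes, lymphocytes, red blood cells, luminal epithelium, myoepithelium, fibroblasts and adipocytes, endothelium and skin keratinocytes. The 29 with at least 3 members detected were tested; no mitochondrially encoded gene was in the table. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 29 lists of a comparison. The adjusted p with an estimated correlation is given beside it. For members, the adjusted p over all genes and the one adjusted over the list alone are told apart in the text.

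Genes were named by rule. For each LPS comparison these were the 6 largest increases and decreases past the threshold, leaving out placeholder symbols, or the 3 of smallest p in a direction where none passed, and the 2 members of smallest p among those passing in each list. For the other comparisons they were the 3 largest increases and decreases, and the same choice of members in the 5 lists of smallest p. Csn2, Lalba, Fasn, Lcn2, Cd14, Nfkbia and S100a8 were named whatever their outcome, and so were the 3 genes of smallest adjusted p in each direction in the authors' deposited tables. Some genes that the rule names are not reported here. Other names are said to have been chosen after their values were seen. Library measures (shares of normalised counts, mean values of marker lists) were compared by exact permutation of the libraries, two-sided, and adjusted by Benjamini-Hochberg over the 55 comparisons made. Computations outside limma used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

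Alternative settings chosen then were no filter, a filter at a mean of 5, no trend, robust moderation, quantile normalisation, centring each library on the same median, weights per library, unadjusted p, fitting 1 day alone, leaving out each library in turn, an estimated correlation, and fry. Alternatives added after seeing the data were a filter at a mean of 6.5, log2 of the normalised count plus 1, that filter or the fit of 1 day without P11 saline library 2, and testing the lists under every alternative of the gene counts. Planned fits with the dam as a block could not be run. Each comparison was repeated on 100 splits of its libraries into groups of the same sizes, the real one included. The model was tested on simulated data with the same 14022 genes and 5 libraries per group, in which 200 genes were changed, 100 by a log2 size of 1 and 100 by 2. The changed genes were drawn only from those with a mean value above 6.5, and noise was drawn independently for each gene and library. The shares found therefore do not cover genes below 6.5, where all genes called for LPS lie. In the LPS comparisons at P10 and P11, 62% and 73% of changes of size 1 and 92% and 95% of those of size 2 were found, with 14 and 19 false calls. For the difference of the effects the shares were 38% and 82%, with 3 false calls; for P11 against P10 they were 65% and 91% in saline dams with 5 false calls, and 63% and 91% in LPS dams with 11.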

Results

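Lactating Sprague-Dawley rats were injected on postnatal day 10 with lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria that activates Toll-like receptor 4, or with saline. Milk was collected 2 h later (P10) or 24 h later (P11), and RNA was sequenced from its fat layer. Milk fat globules leave the secretory epithelium wrapped in its apical membrane and carry remnants of its cytoplasm, so their RNA is a sample of the milk-producing cell taken without tissue. The question was what an immune challenge of the mother does to her milk. There were 5 libraries in each of 4 groups, 20 in all, from 14 dams. The labels give 3 saline dams and 3 LPS dams that provided milk at both times, but the value columns carry no dam numbers. Read totals per library could not be read from the normalised values, so the depth behind each value is unknown. Between 10743 and 12985 genes were detected per library.

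The time of collection separated the libraries far more than LPS did, as the plot of the leading components shows. The first principal component held 75.9% of the variance and the second 3.44%. Milk protein and globule membrane genes together took 67.3% ± 7.48 (SD, n = 5) of all normalised counts in saline libraries at P10 and 73.1% ± 5.72 in LPS libraries. At P11 the shares were 36.5% ± 16.3 in saline and 33.1% ± 6.21 in LPS libraries. One P11 saline library, number 2, lay with the P10 libraries. Its correlation with each P10 library across genes was 0.976 to 0.986, and with each other P11 library 0.874 to 0.932. Its milk protein share was 64.2%, against 29.6% ± 5.83 in the 4 other saline libraries of that day. Values without this library are given for LPS results at P11 whose direction or call it changes. Log2 differences below are on the deposited scale, which compresses changes of genes near its lowest value, so that for rare genes they are smaller than the ratio of their counts. They follow the scaling between libraries in the deposited values and are not changes in the share of all counts.

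**Figure D1:**
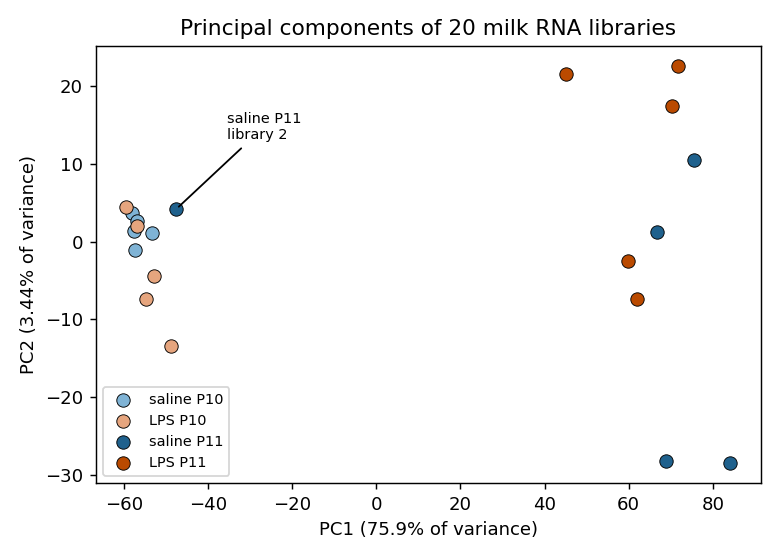
Each point is 1 of the 20 libraries, placed by its scores on the first (x axis) and second (y axis) principal component of the 14022 genes detected. P10 and P11 libraries lie at opposite ends of the first component, which holds 75.9% of the variance, except P11 saline library 2, which lies at -47.6, next to the P10 libraries.

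At 2 h after the injection, small shifts of whole gene groups were seen, while no single gene passed the threshold. Genes of cholesterol synthesis were higher in LPS libraries as a set, with a median log2 difference of 0.32 and positive differences in 20 of 24 members (limma's camera, adjusted p = 3.0e-08; 0.42 with an estimated correlation between genes). Adjusted over the list alone, 3 of them passed. Sc5d, a late enzyme of the pathway, rose by 0.55 ± 0.14 (SE) from 1657 ± 158 to 2485 ± 425 normalised counts (SD, n = 5 per group; limma, list-alone adjusted p = 0.0261). The NF-kB and Toll-like receptor list, the pathway LPS engages, had a median of 0.45 with 18 of 20 members positive (camera adjusted p = 2.3e-06; 0.55 with an estimated correlation). Its mean value per library was 8.95, 9.64, 8.64, 8.86 and 9.82 in LPS libraries and 8.53 to 8.82 in saline libraries, a difference of 0.44 with an exact permutation p = 0.111 (two-sided; adjusted p = 0.218). The STAT3 and involution list had a median of 0.35 with 19 of 22 positive (camera adjusted p = 3.6e-06; 0.55 with an estimated correlation).

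The milk protein list was also higher at 2 h, with a median of 0.37 and 21 of 24 positive (camera adjusted p = 3.6e-04; 0.77 with an estimated correlation). After quantile normalisation its median was 0.0973 and the list was not called (camera adjusted p = 0.406). Cytokines and chemokines had a median of 0.18 (camera adjusted p = 0.0091; 0.77 with an estimated correlation) and immediate early genes 0.54 (0.010; 0.77 with an estimated correlation). The immediate early call was lost without LPS library 1, 2 or 5 (camera adjusted p = 0.139, 0.0990 and 0.111), and the cytokine call without LPS library 1 (0.0608) and with a filter at a mean of 6.5 (0.0580). Red blood cell markers were the 1 list that was lower, at -0.78, with 5 of 6 members negative (camera adjusted p = 0.0023; 0.55 with an estimated correlation). That call was lost with the P10 libraries alone (0.0961) and with the filter at 6.5 (0.306; 0.369 without P11 saline library 2). Haemoglobin transcripts reached 46281 normalised counts in saline library 3 of that day and ranged from 187 to 1658 in the other saline libraries. In the LPS libraries they averaged 438 ± 228 (180 to 712). The group means did not differ past the threshold (exact permutation p = 0.222, adjusted p = 0.370).

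The single genes with the smallest p at 2 h missed the threshold. Il18r1, a subunit of the interleukin-18 receptor, was 158 ± 77.4 in saline and 433 ± 144 in LPS libraries, a log2 difference of 1.13 ± 0.21 (limma adjusted p = 0.539; 0.0401 without saline library 3 and 0.0393 without LPS library 4). Abhd12 differed by 0.59 ± 0.14 (limma adjusted p = 0.844). Tal1 was listed at 0 in all saline P10 libraries and averaged 1.44 in LPS libraries; it passed without LPS library 1 (limma adjusted p = 0.0438). Lower values were seen for Aen, a p53-regulated nuclease (-0.80 ± 0.17, from 2541 ± 669 to 1408 ± 318), Zbtb46 (-0.71) and Lasp1 (-0.52). Within their own lists, Jak2, the kinase bound to the prolactin receptor, differed by 0.43 ± 0.13 (limma, list-alone adjusted p = 0.0361) and Trib3, a stress-induced pseudokinase, by -0.70 ± 0.19 (0.0274). The genes named whatever their outcome gave no difference past the threshold. The log2 differences were 0.41 for Csn2 (beta-casein), 0.55 for Lalba (alpha-lactalbumin), 0.08 for Fasn (fatty acid synthase), -1.21 ± 0.95 for Lcn2 (lipocalin-2), 0.38 for Cd14 (the LPS co-receptor), 0.19 for Nfkbia and 0.45 for S100a8. Of 14022 genes tested with limma, 0 passed an adjusted p of 0.05. There were 622 genes with an unadjusted p under 0.05, where 701.1 are expected by chance, and 1045 when P11 saline library 2 was left out of the shared fit. The authors' deposited table for the same comparison, made with their own DESeq2 test, held 48 genes at that adjusted threshold. Il18r1, Aen and Lasp1 passed there (DESeq2 adjusted p = 0.00621, 0.0281 and 0.0335), as did Sc5d (0.0206). Abhd12, Trib3, Jak2, Lalba and S100a8 were listed but missed it (0.0609, 0.0687, 0.161, 0.112 and 0.36), and Zbtb46 had no adjusted p.

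At 24 h, interferon response genes were lower in LPS than in saline milk as a set. Their median log2 difference was -0.59, with 25 of 26 members negative (limma's camera, adjusted p = 6.7e-12; 0.70 with an estimated correlation). Adjusted over the list alone, 2 passed. Stat2, a transcription factor of the type I interferon pathway, fell by 0.52 ± 0.14, from 2998 ± 634 to 2036 ± 213 normalised counts (limma, list-alone adjusted p = 0.0169). Ddx58, which encodes the RNA sensor RIG-I, fell by 1.15 ± 0.31 (limma, list-alone adjusted p = 0.0169). Without saline library 2 the list's median was -0.94, its camera adjusted p 3.7e-17 (0.41 with an estimated correlation), and 18 members passed over the list alone. The mean value of the list per library was 10.6 ± 0.975 in saline and 9.87 ± 0.541 in LPS libraries (SD). In libraries 1 to 5 it was 10.52, 9.26, 11.88, 10.31 and 11.11 in saline and 10.49, 10.29, 9.94, 9.38 and 9.27 in LPS. Saline libraries 3 and 5, the highest, also had the highest macrophage marker values of the 20 libraries (8.63 and 8.87). The difference of the group means, -0.74, had an exact permutation p = 0.175 (two-sided). Without library 2 it was -1.08, with an exact permutation p = 0.0317 and 0.0728 after Benjamini-Hochberg adjustment over 55 tests of library measures. The mean neutrophil marker value, given for comparison, was 8.13 ± 1.25 in saline and 8.32 ± 0.603 in LPS libraries; without library 2 the saline mean was 8.65 ± 0.554, above that of the LPS libraries (difference -0.33, exact permutation p = 0.429). The mean luminal marker value was higher in LPS libraries by 0.38 (exact permutation p = 0.0079, adjusted p = 0.0312), and by 0.13 without library 2 (p = 0.0159, adjusted p = 0.0485). The NF-kB list had a median of -0.18 (camera adjusted p = 0.0289, and 0.90 with an estimated correlation), and -0.35 without library 2 (camera adjusted p = 8.4e-04, and 0.84 with an estimated correlation). The call was lost without any 1 of saline libraries 1, 3, 4 and 5 (camera adjusted p = 0.0609, 0.229, 0.0535 and 0.110; median -6.9e-04 without library 3) or LPS libraries 3 and 4 (0.0770 and 0.0627), and after quantile normalisation (0.0542), median centring (0.0711), a filter at a mean of 6.5 (0.0655) or log2 of the normalised count plus 1 (0.0539). The mean NF-kB value per library differed by -0.14 (exact permutation p = 0.627, adjusted p = 0.766), and by -0.36 without library 2 (p = 0.0159, adjusted p = 0.0485).

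**Figure D2:**
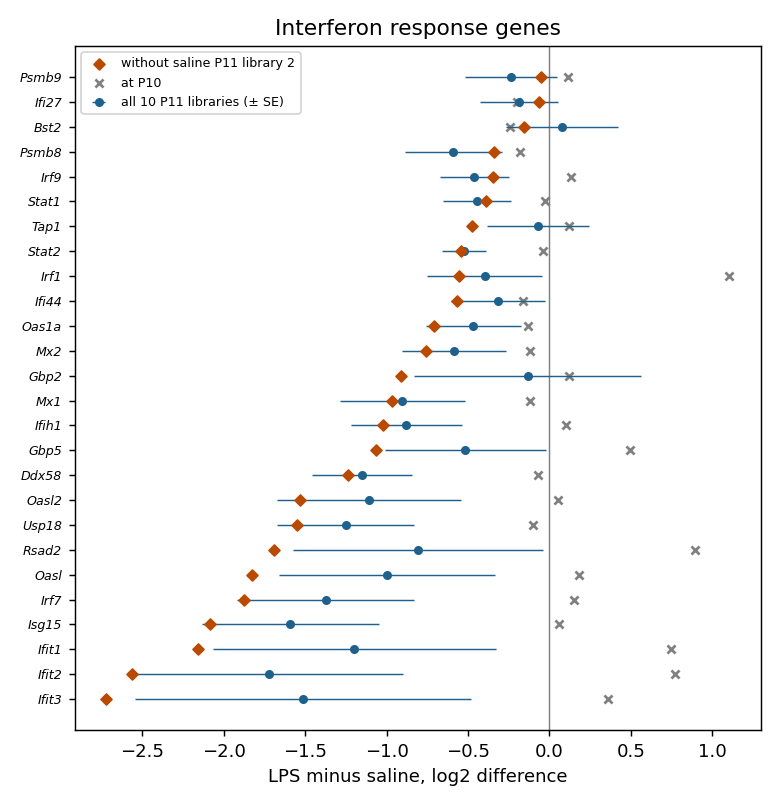
Log2 difference of LPS and saline libraries (x axis) for each of the 26 interferon response genes (y axis): circles with SE, P11 with all libraries; diamonds, P11 without saline library 2; crosses, P10. Most circles and diamonds lie below 0, with medians of -0.59 and -0.94, while the P10 median is 0.08.

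There were 3 further lists that were lower at 24 h with all libraries in the fit, but library 2 set their direction. Nuclear oxidative phosphorylation genes had a median of -0.15 (camera adjusted p = 3.5e-05), ribosomal protein genes -0.09 (3.2e-04) and fatty acid and triglyceride synthesis genes -0.31 (0.0118). With an estimated correlation their adjusted p were 0.91, 0.91 and 0.90. Without library 2 these medians were 0.0733, 0.0726 and 0.16, and the oxidative phosphorylation list was called in the opposite direction, higher with LPS (camera adjusted p = 0.0075; 0.84 with an estimated correlation). Csn2, Lalba and Fasn differed by -0.39, -0.16 and -0.54 between LPS and saline libraries, Lcn2 by 0.09, Cd14 by 0.87, Nfkbia by -0.63 and S100a8 by 1.13. None of these 7 passed, with limma adjusted p from 0.734 to 0.999. Without library 2 the signs of Csn2 (0.0805), Lalba (0.45), Fasn (0.37) and Lcn2 (-0.15) turned, and Cd14 and S100a8 differed by 0.34 and 0.14.

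The 12 genes that passed at 24 h were all higher in LPS libraries and all barely detected. The gene of largest difference, Mxra8, which encodes a membrane protein, had 3.50 ± 4.95 normalised counts in saline and 28.3 ± 10.0 in LPS libraries (0.86 ± 0.15 on the compressed deposited scale, limma adjusted p = 0.016). On the scale of log2 of the normalised count plus 1, Mxra8 differed by 3.51 and missed the threshold (limma adjusted p = 0.0664). P4ha3, a subunit of collagen prolyl hydroxylase, was listed at 0 in every library outside the P11 LPS group and averaged 6.68 ± 1.85 there (0.55 ± 0.04, limma adjusted p = 1.4e-06). Elane, the neutrophil elastase gene, averaged 6.04 ± 3.04 there and was listed at 0 elsewhere (limma adjusted p = 1.4e-04; 0.0721 with the P11 libraries alone). Icos, a co-stimulatory receptor of T cells, Grid2ip and Stc2, a secreted glycoprotein, differed by 0.72, 0.66 and 0.55. Mxra8, Icos and Stc2 missed the threshold without library 2 (limma adjusted p = 0.0562, 0.0562 and 0.0761), and Grid2ip missed it with the P11 libraries alone (0.0760) and after quantile normalisation (0.171). None of the 12 had a mean value of 6.5 or more, and the highest count among them was 45.7. P4ha3, Elane and Stc2 were at the lowest value outside the P11 LPS group, which lowers their SE because the fit shares a single spread over all groups. By the authors' own DESeq2 test Icos passed (adjusted p = 0.0213). P4ha3, Elane, Grid2ip, Mxra8 and Stc2 did not (0.148, 0.231, 0.0709, 0.242 and 0.197). Orm1, an acute phase protein gene, differed by 1.23 ± 0.34 and passed over its list alone (limma, 0.0423), as did the endothelial receptor gene Tek (0.52 ± 0.17, 0.0412), which without library 2 differed by 0.40 and missed it (0.155). The genes lower in LPS libraries with the smallest p, Etnk2 (-0.62), Gria3 (-0.46) and Vps54 (-0.75), missed the threshold (limma adjusted p = 0.088, 0.161 and 0.196), though Etnk2 passed without saline library 3 (0.0138) and Vps54 without saline library 4 (0.0158). Without library 2, 9 genes passed, 8 higher and 1 lower, of which 7 were among the 12. There were 1004 genes with an unadjusted p under 0.05 with all libraries and 1445 without library 2.

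The LPS effect at 24 h was lower than that at 2 h for 8 lists, of which 4 were also called without library 2. With an estimated correlation none passed, and the smallest adjusted p was 0.44 with all libraries and 0.188 without library 2. The 4 were interferon response genes (median difference of the effects -0.88, and -1.08 without library 2), the NF-kB list (-0.66 and -0.78), cholesterol synthesis (-0.29 and -0.41) and STAT3 and involution genes (-0.36 and -0.57), with limma's camera adjusted p of 5.1e-10, 8.1e-08, 6.8e-08 and 0.0233 with all libraries. The 4 not called without library 2 were milk proteins (-0.58, camera adjusted p = 2.5e-05; without it -0.10, 0.272), fatty acid synthesis (-0.38, 8.7e-04; without it 0.14, 0.602), oxidative phosphorylation (-0.16, 8.6e-05; without it 0.0765, 0.0932) and ribosomal proteins (-0.0739, 0.0328; without it 0.0976, 0.0606). The STAT3 call was lost without any 1 of LPS P10 libraries 2 and 5, saline P11 libraries 1, 3, 4 and 5, and LPS P11 library 3 (camera adjusted p from 0.0665 to 0.165), and after quantile normalisation (0.148). Lists called only without library 2 were cytokines (-0.32), immediate early genes (-0.88), the unfolded protein response (-0.43), tight junctions (-0.41) and heat shock genes (-0.28). Their adjusted p with an estimated correlation were 0.188, 0.318, 0.304, 0.432 and 0.559. Of single genes, 5 passed (limma), all near the detection limit: Grid2ip (0.99 ± 0.11, adjusted p = 2.6e-04), P4ha3 (0.55), Aox2 (0.64), and, outside the naming rule and chosen after their values were seen, Elane (0.51) and Vsig1 (0.46). Without library 2 Vsig1 missed the threshold (limma adjusted p = 0.0814). P4ha3 missed it after quantile normalisation (0.121) and median centring (0.293), and Aox2 after both (0.399 and 0.490), without a trend (0.0757) and with weights per library (0.0626). There were 635 genes with an unadjusted p under 0.05, and 1203 without library 2.

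Between 2 h and 24 h, milk from saline dams lost transcripts of secretion and gained transcripts of leukocytes, stress and inflammation. Of 14022 genes, 6557 passed (limma), 3588 higher and 2969 lower at P11. Without library 2, 7956 passed, 6503 of them shared in the same direction. With an estimated correlation none of the 17 list calls in saline dams, given here and in the next paragraph, passed (adjusted p of at least 0.39). The fatty acid and triglyceride list fell as a set, with a median log2 difference of -2.53 (limma's camera, adjusted p = 1.6e-06), with 20 of 24 members lower and 3 higher. Fasn fell by 4.14 ± 0.80 (limma adjusted p = 5.0e-04). Gpat4, which starts glycerolipid assembly, fell by 1.79 ± 0.28, from 26672 ± 9196 to 7965 ± 4325 normalised counts, whereas Dgat2 rose by 3.57 ± 0.63, from 34.0 ± 15.6 to 1663 ± 1127. Milk protein and globule membrane genes fell too, with a median of -2.17 (camera adjusted p = 8.2e-08), with 15 of 24 lower and 1 higher. Among them Folr1, the folate receptor, fell by 2.39 ± 0.37, and Lpo, lactoperoxidase, by 2.41 ± 0.44. Lalba fell by 2.76 ± 0.59, and missed the threshold when no gene was filtered out (limma adjusted p = 0.0882). Csn2 had a log2 difference of -2.14 ± 2.43 and missed the threshold (limma adjusted p = 0.496). Without the mean-variance trend its limma adjusted p was 4.3e-04, and with robust moderation that kept the trend 5.4e-04. The call for Csn2 therefore depends on how the variance is moderated. Its share of all counts was 21.5% ± 3.05 at P10 and 11.4% ± 5.64 at P11. Lactose synthesis genes (median -0.76, 8 of 13 lower), prolactin and STAT5 signalling (-1.03, 6 of 12 lower), ribosomal proteins (-0.56, 49 of 61 lower) and oxidative phosphorylation (-0.99, 71 of 77 lower) fell as sets (camera adjusted p = 0.0019, 0.0034, 3.1e-12 and 6.4e-20). These falls hold on the scaling of the deposited values. The shares of all counts that these lists took were not computed. Rps28 and Rplp1 fell by 1.37 and 0.99, and Cox7a2 and Ndufb2 by 0.89 and 1.65. Enpp2, the autotaxin gene, had the largest fall at 4.65 ± 0.80. Hba1, a haemoglobin gene that shares reads with its near-identical copies, fell by 4.18 ± 0.93.

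Neutrophil markers rose in saline milk by a median of 2.78, with 9 of 14 members higher (limma's camera, adjusted p = 0.0024; 0.39 with an estimated correlation). S100a8, a calcium-binding protein abundant in neutrophils, rose by 4.33 ± 0.71, from 32.6 ± 12.9 to 3651 ± 3364 normalised counts. Macrophage and monocyte markers had a median of 0.63 with 7 of 16 higher (camera adjusted p = 0.0166; 0.0616 after quantile normalisation). Interferon response genes rose by a median of 1.60, with 20 of 26 higher (2.3e-04), among them Oasl (3.78 ± 0.66) and Ifi44 (1.69 ± 0.29). NF-kB genes (1.13, 15 of 20 higher, 0.0018), cytokines and chemokines (0.95, 15 of 30 higher, 0.0031), STAT3 and involution genes (1.15, 15 of 22 higher, 5.2e-04) and immediate early genes (1.70, 9 of 16 higher, 0.0031) rose as sets. So did the heat shock list (1.70, 7 of 8 higher, 0.0018), the unfolded protein response (1.04, 14 of 18 higher, 0.0024), tight junctions (0.90, 7 of 11 higher, 0.0470) and, narrowly, acute phase and antimicrobial genes (0.30, 9 of 22 higher, 0.04996). The tight junction and acute phase calls were each lost without any 1 of several libraries, with the largest camera adjusted p of 0.0632 (saline P10 library 3 left out) and 0.0885 (saline P10 library 2 left out). Cd14 rose by 2.10 ± 0.52, while Lcn2 had a difference of 2.03 ± 0.95 (limma adjusted p = 0.086) and Nfkbia of 0.04. The largest increases were of Clca4l (6.87 ± 0.83), the annexin gene Anxa2 (6.13 ± 0.74, from 299.8 ± 118 to 44068 ± 26022 normalised counts) and Slfn4 (5.61 ± 0.97), a member of a gene family whose copies can share reads.

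In LPS dams most genes past the threshold moved as they did in saline dams, and camera called fewer lists (10 against 17, and 15 without P11 saline library 2). With fry the order turned, with 24 lists called in LPS dams and 22 in saline dams. There were 7413 genes past the threshold (limma), 4332 higher and 3081 lower. In all, 5649 genes passed in both saline and LPS dams, and 5647 of them went the same way. Of these, 3086 were higher in both, against 1108 expected for independent lists, and 2561 lower, against 652. The comparisons share no library, but both use the same fitted spread per gene. Their lists are therefore not independent, and the expected counts are only a rough guide. With an estimated correlation none of the 10 lists called in LPS dams passed (adjusted p of at least 0.50). Lists that fell as sets had median log2 differences of -3.01 (fatty acid synthesis), -2.78 (milk proteins), -1.12 (oxidative phosphorylation), -0.62 (ribosomal proteins), -1.07 (prolactin and STAT5 signalling), -0.99 (lactose synthesis) and -0.53 (cholesterol synthesis) (limma's camera, adjusted p = 2.5e-08, 3.2e-10, 1.4e-22, 2.1e-13, 0.0019, 0.0022 and 0.0040). After quantile normalisation the ribosomal median was -0.17 and that list was not called (camera adjusted p = 0.0679). The cholesterol call was lost at a mean of at least 6.5 without library 2 (0.0636). Fasn fell by 4.76, Olah, the thioesterase that releases medium-chain fatty acids, by 3.27, Muc15 by 3.48, Folr1 by 3.05 and Gpat4 by 2.17. Erbb4 and Stat5b, which act in lactogenic signalling, fell by 1.85 and 1.33, Ndufs6 and Atp5mg by 1.23 and 1.54, and Rpl41 and Rplp1 by 0.98 and 1.14. Of the lists called in saline but not in LPS dams, the test of the difference itself was past the threshold for the interferon, NF-kB and STAT3 lists (adjusted p = 0.44, 0.44 and 0.71 with an estimated correlation). It was not for cytokines (camera adjusted p = 0.118), immediate early genes (0.106), tight junctions (0.271), acute phase genes (0.756) and macrophage markers (0.371). Without library 2 the first 3 of these passed (1.0e-04, 4.6e-05 and 0.0140; at least 0.188 with an estimated correlation). The calcium pump gene Atp2b2 fell by 4.39 ± 0.73 and Angptl1 by 4.67 ± 0.56. Neutrophil markers (2.63, 11 of 14 higher), heat shock genes (1.62, 7 of 8 higher) and the unfolded protein response (0.84, 12 of 18 higher) rose as sets (camera adjusted p = 0.0028, 0.0102 and 0.0460; the last was lost without any 1 of several libraries, with 0.0761 at most, LPS P10 library 4 left out). Ctgf, a matricellular growth factor gene, rose by 6.59 ± 0.71 from 41.8 ± 30.5 to 11026 ± 4886 normalised counts, Clca4l by 6.84, Anxa2 by 6.75, S100a8 by 5.01 ± 0.71, Lcn2 by 3.33 ± 0.95 and Cd14 by 2.59 ± 0.52. Lalba fell by 3.46. Csn2 (-2.94 ± 2.43, limma adjusted p = 0.323; 2.3e-05 without the trend) and Nfkbia (-0.79) missed the threshold.

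**Figure D3:**
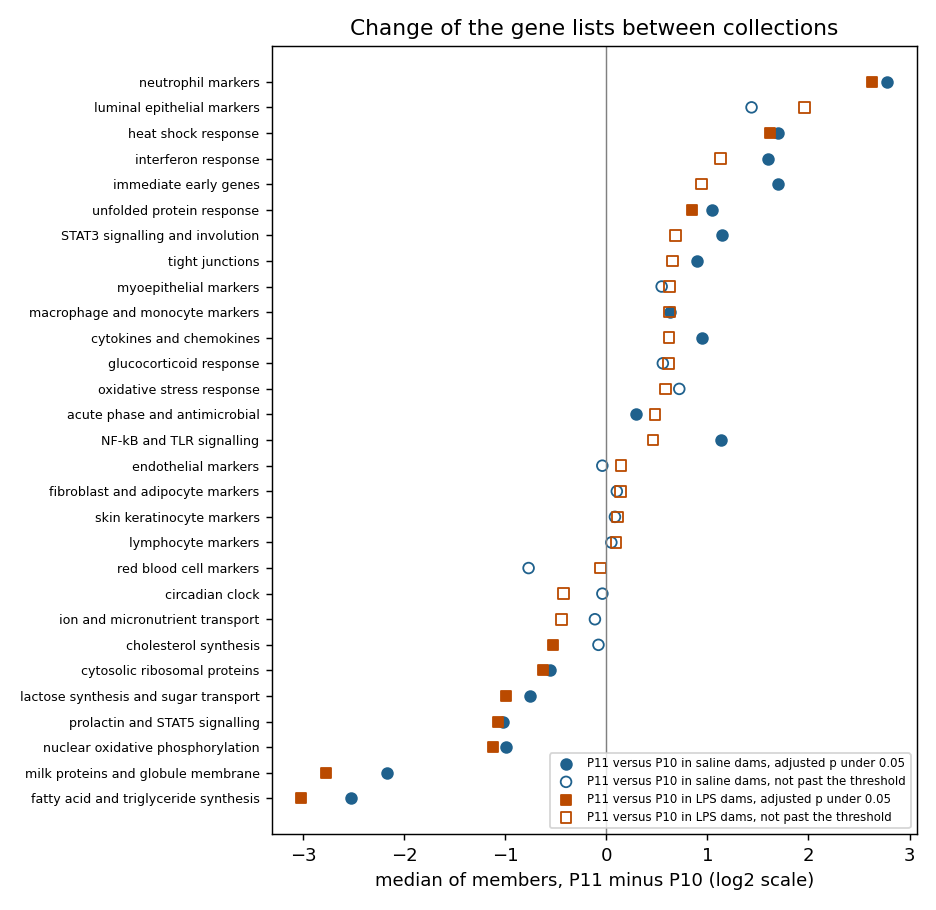
Median log2 difference between P11 and P10 (x axis) of the 29 gene lists (y axis) in saline dams (circles) and LPS dams (squares), filled where the camera adjusted p was under 0.05. Fatty acid synthesis and milk protein lists lie lowest, at -2.53 and -2.17 in saline dams, and neutrophil markers highest, at 2.78.

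Markers of the epithelium itself moved with these groups. The luminal list as a whole missed the threshold in saline dams (median 1.44, camera adjusted p = 0.149), with 5 of 7 members higher and 2 lower. The keratin gene Krt19 rose by 3.73 ± 0.53 and Cdh1, encoding E-cadherin, by 2.54 ± 0.39, while the transcription factor genes Elf5 and Ehf fell by 2.19 ± 0.42 and 1.22 ± 0.24; these 4 were chosen after their values were seen. The mean luminal value per library was 12.8 ± 0.185 in saline P10, 12.9 ± 0.155 in LPS P10, 13.9 ± 0.547 in saline P11 and 14.2 ± 0.043 in LPS P11 libraries. The neutrophil value was 6.001 ± 0.149 in saline and 6.18 ± 0.363 in LPS libraries at P10. The share of counts in ribosomal RNA genes was 0.415% ± 0.0602 in saline P10 and 1.96% ± 1.70 in saline P11 libraries (exact permutation p = 0.0159, adjusted p = 0.0485), and 0.522% ± 0.360 and 2.43% ± 2.47 in LPS libraries (p = 0.0238, adjusted p = 0.0569). Between collections the neutrophil value rose by 2.14 in LPS dams (exact permutation p = 0.0079, adjusted p = 0.0312, n = 5 per group) and differed by 2.13 in saline dams (exact permutation p = 0.0238, adjusted p = 0.0569). The smallest p that 5 against 5 libraries allow is 0.0079. After centring every library on the same median, the split of genes higher and lower at P11 was 2478 and 5035 in saline dams and 2696 and 5206 in LPS dams. Centring shifted the log2 differences by -0.22 and -0.27.

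**Figure D4:**
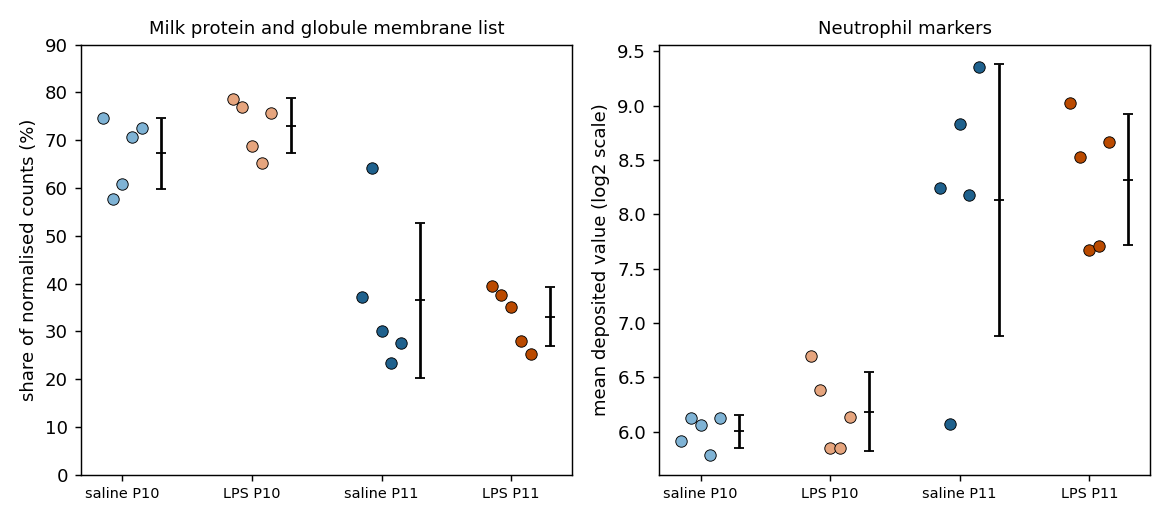
Left, share of normalised counts taken by milk protein and globule membrane genes (percent); right, mean value of the neutrophil markers (log2 scale), for each library in the 4 groups (x axis), with the group mean and its SD beside the points. The milk share was 67.3% in saline P10 and 36.5% in saline P11 libraries and the neutrophil value 6.001 and 8.13; the P11 saline point beside the P10 libraries is library 2.

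The authors' deposited tables list genes with an unadjusted p under 0.05 for LPS against saline at each time. The table for P10 holds 1024 genes, 611 higher and 413 lower with LPS, and 48 have an adjusted p under 0.05, 34 higher and 14 lower. In the authors' deposited table the strongest increases were of Ace, the angiotensin-converting enzyme gene (log2 fold change 1.68, adjusted p = 2.5e-06), Csn1s2b, a casein gene (1.73, 8.2e-06) and Echdc1 (0.93, 4.9e-05). The strongest decreases in the authors' deposited table were of Oplah (-0.59, adjusted p = 0.0044), Meis3 (-1.99, 0.0062) and Tenm3 (-2.39, 0.0107). In the limma fit these 6 differed by 1.46, 1.66, 0.90, -0.57, -0.67 and -0.88 on the compressed scale, and none passed (limma adjusted p of at least 0.844). That fit shares its spread with the P11 libraries. With P11 saline library 2 left out of it, the adjusted p were at least 0.169 (Tenm3), and again none passed. Meis3 had 44.5 ± 15.2 normalised counts in saline and 11.2 ± 4.25 in LPS libraries, and Tenm3 51.1 ± 19.2 and 9.94 ± 8.18, so the smaller limma values for these rare genes belong to the scale. The table for P11 holds 1085 genes, 477 higher and 608 lower, of which 19 have an adjusted p under 0.05, 8 higher and 11 lower. The leading genes in the authors' deposited table for P11 were the secretoglobin gene Scgb2a2 (1.87, adjusted p = 3.4e-04), RGD1307461 (6.195, 0.0051) and Oprpn (1.82, 0.0051) on the higher side. On the lower side the authors' deposited table led with MGC105649 (-0.75, adjusted p = 0.0013), Sstr3 (-3.33, 0.0071) and Abcg4 (-1.22, 0.0184). In the limma fit of all libraries, MGC105649 had the opposite sign at 0.14, and without library 2 it was -0.75. RGD1307461 passed without library 2 (limma adjusted p = 0.0475; 0.111 with all libraries). The base means of that table were matched by a mean of the other 9 P11 libraries. The weight of saline library 2 was 6.5e-05, against 0.139 to 0.145 for each of the others.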

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

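Of the tests below, the swap with a P10 library, added leukocytes, rescaling by the milk transcripts, whole cells, and the interferon difference without the P10-like library were chosen after the result was seen; the others were set before. Libraries were picked out where one lay far from the other 4 of its group; chance does this in about 1 in 20 groups. It occurred in 13 of 80 groups of library measures. The measures were genes detected in LPS P11 library 1 (12985), the Csn2 share in saline P11 library 2 (21.2%), the ribosomal RNA share in LPS P11 library 5 (6.79%), haemoglobin in saline P10 library 3 (46281 normalised counts), and the median of detected genes in saline P10 library 1 (8.38). The luminal value in saline P11 library 2 (12.9), the myoepithelial value in saline P10 library 3 (7.14), the NF-kB value in saline P10 library 2 (8.53), and the first component in saline P10 library 3 (-53.4) and saline P11 library 2 (-47.6) also stood apart. So did 3 measures of likeness of saline P11 library 2 to the P10 libraries: its mean correlation with them (0.981) and its position between the days over all genes (0.077) and over abundant genes (0.075), where 0 is P10 and 1 is P11.

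Among the named genes, 38 of 263 groups had such a library, where chance gives about 1 in 20. Saline P11 library 2 stood apart in 16 genes, library 3 in 3 and library 4 in 1. The counts were 3, 1, 3 and 1 for LPS P10 libraries 1, 2, 3 and 5; 3, 1, 1 and 2 for LPS P11 libraries 2, 3, 4 and 5; and 1 and 2 for saline P10 libraries 2 and 3.

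The LPS effect differed between the days by the test of the difference itself (limma) in 5 genes: Grid2ip (0.99), P4ha3 (0.55), Aox2 (0.64), Elane (0.51) and Vsig1 (0.46). It also differed in 8 lists (camera): interferon response (-0.88), NF-kB (-0.66), milk proteins (-0.58), fatty acid synthesis (-0.38), STAT3 (-0.36), cholesterol synthesis (-0.29), oxidative phosphorylation (-0.16) and ribosomal proteins (-0.0739). For the 5 genes 2 of 100 splits gave as many, the real one included, and the highest of the other splits also gave 5. All 5 lie near the lowest value and are among the 12 genes called at P11. For those 12, 9 of 100 splits gave as many, so the count of 5 does not exclude chance. For the 8 lists chance cannot be excluded: 58 of 100 splits gave as many, and the highest other gave 16.

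Saline P11 library 2 lay with the P10 libraries. A swap with a P10 library would place one of those with P11, but the highest P10 position was 0.069, which argues against it. Fewer usable reads would lower the number of genes detected and act on rare genes. The library had the fewest genes detected of all 20 (10743, against at least 10819 in P10 libraries), which goes with fewer reads. Its position over abundant genes was still 0.075, which argues against fewer reads as the reason for its place. A P10 milk sample under a P11 label stays open: its position of 0.077 lies near the P10 range of -0.025 to 0.069, against 0.796 to 1.13 in the other P11 libraries, and a dam whose milk had not changed by 24 h would look the same. Over abundant genes the highest P10 position was 0.037, below the 0.075 of this library. The biological alternative, a dam whose milk had not changed, was not tested.

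Many genes differed between P11 and P10. For saline dams chance can be excluded for genes (6557, 1 of 100 splits as many, highest other 6537, which exchanged P10 library 1 for P11 library 2). For the 17 lists in saline dams, 3 of 100 splits gave as many, the real one included, and the highest other also gave 17. None of these lists passed with an estimated correlation, so chance is not firmly excluded for them. For LPS dams chance can be excluded for genes (7413; 1 of 100 splits, highest other 2) but not for lists (10; 45 of 100, highest other 16). Leukocytes added to otherwise equal RNA would raise no luminal gene, whereas 5 of 7 luminal markers were higher past the threshold in each treatment and 2 lower, with a median change of 1.87 ± 0.087 (SE; 9 P11 libraries without library 2 and 10 P10 libraries); camera did not call the list. A rescaling by the falling milk transcripts would move all other genes alike. Among abundant genes the oxidative phosphorylation list changed by -0.998 ± 0.0837 (SE) relative to the others. No factor per library makes such a difference. That list had the smallest camera p of the lists tested in saline and LPS dams (adjusted p = 6.4e-20 and 1.4e-22). Its difference from other genes was therefore known when it was picked. The value shows only that rescaling is not the sole cause for this list. Whether rescaling made smaller shifts, such as the ribosomal medians of -0.56 and -0.62, was not tested. Whole cells besides globule RNA would raise luminal, myoepithelial, neutrophil and macrophage markers together; their median changes were 1.87, 0.61, 2.88 and 0.72 (lowest 0.61), so this remains a candidate explanation beside the untested effects of the earlier milking and of the day of lactation.

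The interferon list was lower in LPS than in saline milk at P11. The P10-like saline library cannot have made the difference, since without it the median was -0.94. Without that library and with the neutrophil value as covariate, the difference of the mean interferon value was -0.90 (95% interval -1.87 to 0.08), and with the macrophage value -0.91 (-1.87 to 0.05), against -1.08 (-2.06 to -0.10) without either, so fewer leukocytes in LPS milk cannot be told apart from lower interferon signalling with so few libraries. Chance cannot be excluded: 8 of 100 splits gave as small a p, the real one being 2.3e-13 and the smallest other 1.0e-18. An effect of LPS itself, the biological explanation in the design, stays open.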

How the results depend on the processing

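The filter at a mean of 6.5, log2 of the normalised count plus 1, the settings that combine a filter or 1 day with leaving out P11 saline library 2, and the lists under the settings of the gene counts were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because the deposited columns carry no dam numbers; the dam as a random block, as a fixed effect, and as a block in the list tests were not run. The filter at a mean of 5 removes no gene and tests nothing.

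Among counts of genes, 131 stayed within 1.5 times the reported count and 27 moved. For LPS at P10 (0 genes, limma) an unadjusted p gave 622. For LPS at P11 (12 genes) the counts were 5 without a trend, 2 after quantile normalisation, 3 after median centring, 4 with weights per library, 2 with that day alone, 1 with that day alone without library 2, 0 at a mean of at least 6.5 with or without library 2, and 1004 at an unadjusted p. For the difference of the LPS effects (5 genes) they were 2, 1, 1 and 3 under the first 4 of these, 0 at a mean of at least 6.5 with or without library 2, and 635 unadjusted. The filter at 6.5 removes every gene called, since all lie below it. The full fit shares a single spread per gene over the 4 groups. P4ha3, Elane, Stc2 and Vsig1 were at the lowest value in every library outside the P11 LPS group, which lowers their SE in that fit. The fit of that day alone takes no spread from the P10 libraries. The cause of the other changes was not tested. Leaving out 1 library at a time gave 0 to 1, 9 to 27, 4 to 10, 5730 to 7956 and 6877 to 7944 genes for LPS at P10, LPS at P11, the difference, and P11 against P10 in saline and LPS dams. For LPS at P11 the counts were 27 without saline library 3, 24 without saline library 4 and 22 without LPS library 3.

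Among counts of lists, 142 stayed within 1.5 times and 21 moved. With an estimated correlation 0 lists passed in every comparison, and with fry 0 passed in the LPS comparisons and their difference (limma; 7, 5 and 8 by camera). For LPS at P11 (5 lists) quantile normalisation gave 1, weights 3, and both settings without library 2 added to a filter or to that day alone gave 9. For the difference (8) quantile normalisation gave 5 and the filter at 6.5 without library 2 gave 13. For P11 against P10 in LPS dams (10) there were 17 without the filter, 18 after centring and 24 with fry. Leaving out 1 library gave 5 to 11, 3 to 8, 6 to 11, 15 to 17 and 9 to 15 lists in the order above.

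Single lists reversed by camera's direction in 20 cases, all in LPS at P11 or the difference; the cause was not tested beyond library 2. In the difference the fatty acid list (-0.38) kept that direction and lost its call, though its median turned to 0.14 with weights and in both fits without library 2 (camera adjusted p = 0.596, 0.602 and 0.794). For LPS at P11 the ribosomal list (-0.09) was 0.0362 after quantile normalisation, 0.0408 with weights, and 0.0726 without library 2 in the full fit, at a mean of at least 6.5 and in that day alone. The fatty acid list (-0.31) was 0.10 with weights and 0.16 in each of the fits without library 2. Oxidative phosphorylation (-0.15) was 0.0592 with weights and 0.0733, 0.0770 and 0.0733 in those fits. In the difference, the ribosomal list (-0.07) was 0.11 after quantile normalisation, 0.0819 with weights and 0.10 in both fits without library 2, and oxidative phosphorylation (-0.16) was 0.0588 with weights, 0.0765 without library 2 and 0.0837 with the filter at 6.5 as well. Over all libraries left out in turn, the P11 medians ranged from -0.19 to 0.0726 for the ribosomal list, -0.63 to 0.16 for fatty acids and -0.25 to 0.0733 for oxidative phosphorylation, and in the difference from -0.18 to 0.10 and -0.26 to 0.0765 for the ribosomal and oxidative lists. Of 1521 list values in all, 1348 kept direction and side of the threshold and 153 were weaker, 47 of these with the estimated correlation and 20 with fry.

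Of 3282 values of named genes, 3189 kept direction and side of the threshold, 68 were weaker and 25 stronger. Stc2, Icos and Mxra8 at P11 lost the threshold without library 2 (limma adjusted p = 0.0761, 0.0562 and 0.0562), while P4ha3, Elane and Grid2ip passed (2.1e-05, 9.4e-04 and 0.0018). With that day alone Elane and Grid2ip missed it (0.0721 and 0.0760; 0.231 and 0.242 without library 2 as well), and P4ha3 passed (0.0026 and 0.0171). Csn2 passed between P10 and P11 without a trend, with robust moderation and at a mean of at least 6.5 (limma adjusted p = 4.3e-04, 5.4e-04 and 0.0054 in saline dams). Depth per library is unknown, so its limits could not be measured; the 12 genes called at P11 had at most 45.7 normalised counts.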

Other observations

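Of the results here, none of the splits was chosen after the result was seen; the examples of genes were. In several lists single genes passed between P10 and P11 although the list did not. In saline dams 7 of 13 oxidative stress genes were higher, 4 lower and 2 not past the threshold: Gpx2 rose by 5.14 and Hmox1, haem oxygenase 1, by 3.54, while Gpx1 fell by 2.80. The list had a median of 0.72 (camera adjusted p = 0.164) in saline and 0.59 (0.493) in LPS dams. Of 15 clock genes 2 were higher, 5 lower and 8 did not pass in saline dams: Bhlhe40 rose by 1.44 and Cry2 by 1.03, and Arntl fell by 1.72 and Npas2 fell by 2.14, with list medians of -0.04 (0.254) and -0.42 (0.0653). Of 15 glucocorticoid targets 5 were higher, 5 lower and 5 did not pass: Dusp1 rose by 3.47 and Errfi1 by 1.92, and Fkbp5 fell by 2.12 and Zbtb16 fell by 3.31, with list medians of 0.56 (0.869) and 0.61 (0.783). In ion transport 2 of 17 genes were higher, 6 lower and 9 did not pass; Slc12a2 rose by 1.30 and Aqp3 fell by 2.21 (list -0.11, 0.164; LPS dams -0.44, 0.0868). Of 10 myoepithelial markers 5 were higher, 1 lower and 4 did not pass; Acta2 rose by 2.63 and Krt17 by 5.21, and Mylk fell by 0.99, with list medians of 0.55 (0.0745) and 0.63 (0.0653).

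In LPS dams the remaining lists were not called by camera: NF-kB 0.46 (adjusted p = 0.495), cytokines 0.62 (0.0653), interferon 1.13 (0.326), STAT3 0.68 (0.0649), immediate early 0.94 (0.0709), tight junctions 0.66 (0.209), acute phase 0.48 (0.0653), macrophage 0.63 (0.0718) and luminal 1.96 (0.180). With P11 saline library 2 left out of the shared fit, 4 of these were called: cytokines (0.0324), STAT3 (0.0245), immediate early (0.0324) and acute phase (0.0369), each with an adjusted p of at least 0.40 with an estimated correlation. The clock list was then also called, as lower (0.0417; 0.43 with an estimated correlation). Cholesterol synthesis in saline dams had a median of -0.08 (0.413). Lymphocyte markers had medians of 0.05 and 0.10 (saline and LPS dams; camera adjusted p = 0.835 and 0.995), red blood cell markers -0.77 and -0.06 (0.254 and 0.856), fibroblast and adipocyte markers 0.10 and 0.14 (0.835 and 0.782), endothelial markers -0.04 and 0.14 (0.869 and 0.560), and keratinocyte markers 0.09 and 0.11 (0.544 and 0.356). At P10 the lists that LPS did not move past the threshold had medians between -0.08 and 0.22. The lowest was prolactin and STAT5 signalling at -0.08 (camera adjusted p = 0.894), where the test's direction was up, and the highest tight junctions at 0.22 (0.116). The acute phase list had 0.18 (0.0772) and the interferon list 0.08 (0.394). With P11 saline library 2 left out of the shared fit, the acute phase list (camera adjusted p = 0.0236) and the unfolded protein list (median 0.20, 0.0053) were called as higher at P10. Both had an adjusted p of 0.49 with an estimated correlation. At P11 the glucocorticoid, immediate early, unfolded protein and heat shock lists had positive medians while the test's direction was down, and none was called. Without P11 saline library 2, the immediate early list (median -0.28, camera adjusted p = 0.0283) and the unfolded protein list (-0.23, 0.00846) were lower with LPS at P11, both with an adjusted p = 0.84 with an estimated correlation.

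Without P11 saline library 2, interferon genes with large differences at P11, chosen after their values were seen, were Ifit3 (-2.72), Ifit2 (-2.56) and Isg15 (-2.08).

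Other splits of the libraries were counted for the LPS comparisons. At P10, 0 genes were called with limma (622 at an unadjusted p under 0.05). All 100 of 100 splits therefore had to give as many (highest other 66), and the count cannot test chance. For the lists at P10 chance cannot be excluded (7; 41 of 100, highest other 18). At P11 it cannot be excluded for genes (12; 9 of 100, highest other 123) or lists (5; 82 of 100, highest other 15). Some splits called many more genes than the real one, 66 against 0 and 123 against 12. A structure among the libraries of a day that the treatment does not follow could give this. Whether such counts exceed what chance gives among correlated genes was not tested. The labels name no batch that would account for such a structure.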
